A study of Danio rerio with 12 samples.

How the data were processed

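The series compared whole zebrafish larvae exposed to silver with control larvae on 2-colour Agilent microarrays, on which RNA from an exposed sample and RNA from a control sample compete for the same probes. Per the labels, the fish were wild type of the AB strain, 21 days old, and were kept from 6 days post fertilization for 15 days in conditioned water with silver nitrate (AgNO3), with silver nanoparticles (AgNPs), each at 0.01 mg/L, or without silver. The 12 arrays held 6 AgNO3 and 6 AgNPs samples, each against a control sample. In each group, 3 arrays carried the exposed RNA in Cy5 and 3 carried it in Cy3. The labels call the samples biological replicates, but how many tanks each group had is not given in the sources used here, so p-values measure only the spread between these samples. The sample codes in the labels were read as 6 control samples, each used on 1 AgNO3 and 1 AgNPs array.

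The deposited values were log ratios of both channels per probe, taken here as log2, with 43603 probes on each array. The base is an assumption: values reached -8.02 and 7.67, and the labels do not name it. Per the labels' protocols, RNA was extracted with Trizol and labelled with cyanine dyes; the scanner software, background correction, normalization and spot filter are not given in the sources used here. Between 6.97% and 10.9% of the values of an array were empty, and array medians lay between -0.0093 and 0.015, so the arrays were taken as centred by the authors. Intensities were not used here, so signal over background is unknown, and the number of arrays limits the precision.

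The sources do not say whether the values of dye-swapped arrays had been turned. Of the planned checks, that on control spots could not be run. The correlation of residuals between arrays sharing a control sample averaged 0.0206 over 6 pairs against -0.0100 for other pairs (2-sided exact permutation p = 0.694 over 36 permutations), which left the matter undecided. Arrays of 1 dye orientation correlated at 0.125 within AgNO3 and 0.142 within AgNPs, and arrays of opposite orientation at -0.0438 and -0.0430. A further check, chosen after seeing the data, used different probes of the same gene, which share the gene's change but not probe-specific dye bias. Their covariance, summed over all arrays, was highest of 2048 sign patterns with the values as deposited (rank 1), whereas turning the swapped arrays ranked 255. A dye bias common to all probes of a gene would give the same in values that had not been turned, so the check does not settle it. The covariance specific to single probes was 0.0190 (SE 0.00556 over arrays) within an orientation and -0.0150 (SE 0.00758) between orientations. The latter goes with turned values, since dye bias of single probes would make it positive in values not turned, but it lay within 2 SE of 0. Values were therefore used as deposited, as if already turned the same way. Values of arrays with exposed RNA in Cy3 carried at most 6 significant digits and the others 10; the reason is not given in the sources used here.

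Probes were named through the platform annotation, updated by accession, symbol and synonym: 30186 probes had 1 gene symbol and 13417 had none, and no probe had several. Of the named probes, 24749 were named through an accession, 4278 through a current symbol and 1133 through a synonym, and 26 kept their old symbol. Probes of a gene were averaged on the log scale per array, and unnamed probes stayed features of their own, which gave 28497 features. A feature was tested if it had values on at least 2 of the 3 arrays of each orientation in each group, which left 25264 features, 14329 genes and 10935 unnamed probes. No other column of values was left out.

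All 12 arrays entered 1 linear model in limma 3.58.1 (R 4.3.3) with a mean for each exposed group and a dye-orientation term; moderated 2-sided tests were made of each group against 0 and of the difference AgNO3 minus AgNPs. The Benjamini-Hochberg adjusted p threshold was 0.05. The fit was tested on simulated data with the measured spreads, 5 runs. There 47.2% of features shifted by 0.5 in AgNO3 versus control were called, 80.8% of those shifted by 1, 90% of those shifted by 1.5 and 96% of those shifted by 2, with 10.4 false calls per run over 25264 features. The statistics of each of 36 gene lists were tested against those of all other features by limma's camera method with a preset inter-gene correlation of 0.01 (cameraPR, which accepts the missing values). Beside it stood camera with an estimated correlation and fry, on values with gaps filled. Unless said otherwise, fry stands for its test of change in 1 direction. In simulated data, a list shifted by 0.2 was called in 20 of 20 runs, and 0 other lists were. The simulated genes were independent of each other and had the same spread on every array. Members of measured lists were correlated, by an estimate of up to 0.419 for the lens list. The runs therefore do not show how often features or lists are called falsely in these data, or what share of shifted features is found in AgNO3.

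The lists, tests and alternatives, unless said otherwise, and the rule for the genes named were fixed before the data were examined. In each group the rule took up to 12 genes per side past the threshold with at least 5 of 6 arrays going the same way, filled to 8 per side by lowest p and given as values. For the difference it took the 5 genes of lowest p per side. It also took up to 4 members of each list that passed, 3 members each of the metal handling, antioxidant, heat shock, ion transport and clock lists, and mt2, hsp70l and hmox1a. Errors are standard errors (SE) of the model or standard deviations (SD) over arrays, as stated, with 6 arrays per group.

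Alternatives covered the dye term, centring, scaling, missing values, low variation, probe averaging, array weights (limma), robust variance, a size limit of 1 on the log2 scale, blocks by replicate or control number (duplicateCorrelation with statmod 1.5.0), each group alone, the direction of swapped arrays, and each array left out in turn. Leaving out AgNPs replicates 3 to 6 and a test of both exposed groups together were added after seeing the data. Chance values of the correlation between groups were simulated with shared controls, using the control-number correlation of 0.0369 estimated from the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.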

Results

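Gene expression was measured in 21-day-old zebrafish larvae after 15 days in water with silver nitrate, a soluble salt, or with silver nanoparticles, both at 0.01 mg/L, each against unexposed larvae. Particle size, coating and measured silver levels are not given in the sources used here. There were 6 arrays per exposed group, each giving 25264 tested features as log2 ratios of exposed over control larvae. The interquartile range of the log ratios was 0.216 to 0.342 on the AgNO3 arrays and 0.293 and 0.233 on AgNPs replicates 1 and 2, but 0.0946 to 0.116 on AgNPs replicates 3 to 6. The direction exposed over control is likely but not settled: it rests on the usual order of Cy5 over Cy3 on arrays with exposed RNA in Cy5. With the opposite order, every sign given here turns. That dye-swapped arrays had been turned before deposit rests on a check chosen after seeing the data. With those arrays turned, 4 other features passed in AgNO3 and 0 in AgNPs.

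**Figure D1:**
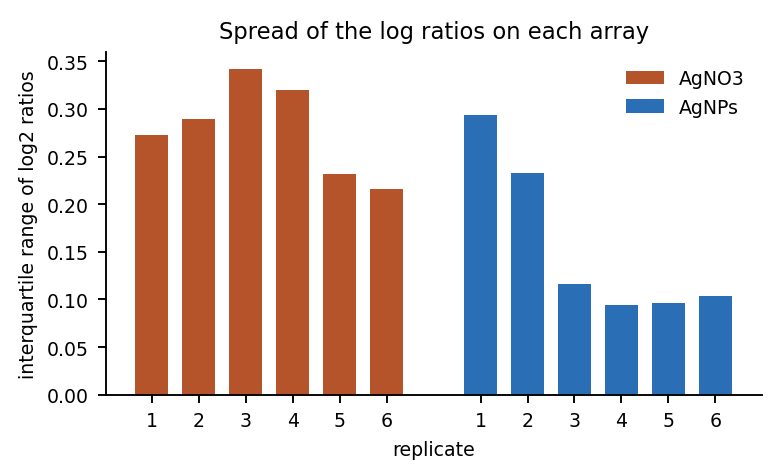
Interquartile range of the log2 ratios on each array (vertical axis) by group and replicate (horizontal axis), 1 bar per array. AgNPs replicates 3 to 6 spanned 0.0946 to 0.116 and the other arrays 0.216 to 0.342.

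The AgNO3 arrays asked what the dissolved silver salt does to larval transcripts. Expression of ace, the angiotensin-converting enzyme that trims peptide hormones, fell by 0.80 on the log2 scale (SE 0.09, n = 6), and that of grna.2, a granulin gene, fell by 0.67 (SE 0.07, n = 6). Both were lower on 6 of 6 arrays, with limma adjusted p = 0.0447 each. A probe without a gene name fell by 0.57 (SE 0.07, adjusted p = 0.0447). No feature rose past the threshold, and 2084 features, 895 higher and 1189 lower, had an unadjusted p under 0.05 against 1263.2 expected by chance. The model estimated 1 spread per feature from all 12 arrays, although the AgNPs arrays had the narrower spread on average. This tends to make p-values too small in AgNO3 and too large in AgNPs. Neither the excess over 1263.2 nor the gap to the 1072 features of AgNPs therefore measures the breadth of a response. These calls were close to the threshold: ace passed in 6 of 24 alternatives and in 0 of the 12 that left out an array, and grna.2 in 8 of 23 and in 1 of 12. Turning the dye-swapped arrays, not counted among these, ended the calls too. On the 6 AgNO3 arrays alone, and with arrays scaled to a common spread, 0 features passed.

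Other genes with the lowest p-values against control did not pass the adjustment (adjusted p 0.0980 to 0.209). Several of them serve the retina: rdh8a, a photoreceptor retinol dehydrogenase, had a log2 ratio of 0.33 (SE 0.06), the green cone opsin opn1mw1 0.46 (SE 0.08), and the photoreceptor potassium channel subunit kcnv2b 0.62 (SE 0.11). On the lower side, pde6ga, the inhibitory subunit of the photoreceptor phosphodiesterase, had -1.64 (SE 0.24) and guca1c, a guanylate cyclase activator of photoreceptors, -0.59 (SE 0.09). As a list, photoreceptor genes did not pass in AgNO3 by camera (adjusted p = 0.0660, and 0.443 with an estimated correlation). The endoplasmic reticulum chaperone hspa5 (BiP) stood at -0.40 (SE 0.06), lower with all 6 of its probes. Values were -0.70 for dhrs13a.2, -0.51 for arid6 and -0.32 for clint1a. The other values on the higher side were 0.47 for tmem237b, a protein of the ciliary base, 0.46 for the synaptotagmin gene syt9b, 0.27 for bambib, an inhibitor of BMP and activin receptors, 0.71 for ppp1r3c2b, a glycogen-targeting subunit of protein phosphatase 1, and 0.29 for zgc:77439.

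**Figure D2:**
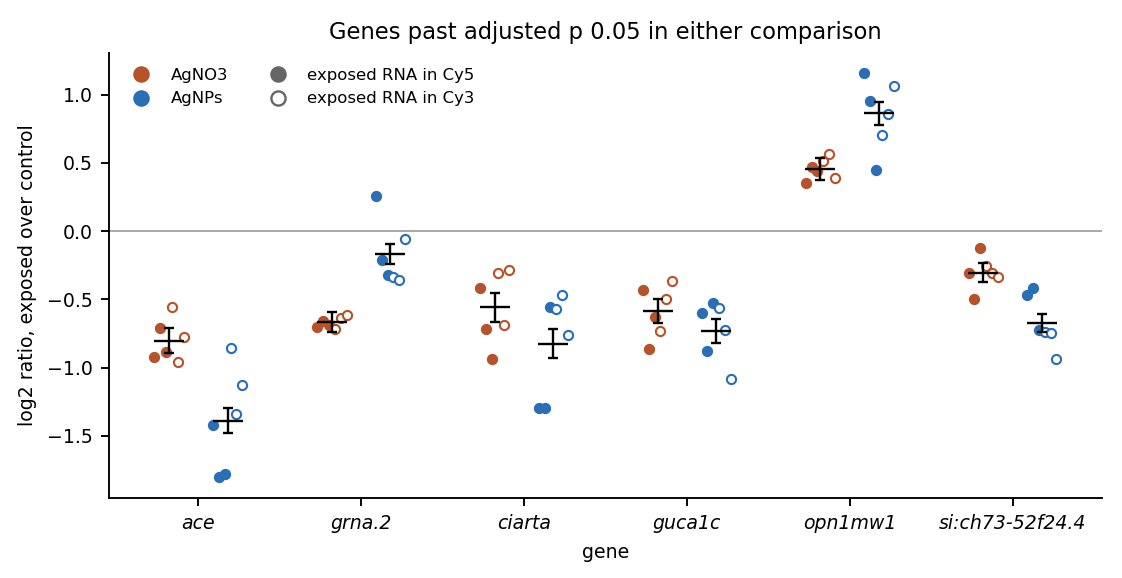
Log2 ratio of exposed over control larvae (vertical axis) for the genes past an adjusted p of 0.05 in either comparison (horizontal axis). Points are arrays, filled with exposed RNA in Cy5 and open in Cy3. The bar and whiskers are the group mean (n = 6) and its SE from the model, whose spread is estimated from all 12 arrays. All 12 points of ace, ciarta and guca1c lie below 0 and all 12 of opn1mw1 above 0.

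Among gene lists, genes for the folding and breakdown of proteins and innate immune genes were lower in AgNO3. Proteasome subunits fell (35 of 44 genes lower, adjusted p = 0.000326; adjusted p = 0.255 with an estimated correlation), with psmc2 at -0.34 (SE 0.08), psmb4 at -0.37 (SE 0.09) and psmd8 at -0.31 (SE 0.09; -0.20 without AgNO3 replicate 5). The value of psmb5 was -0.22, with probes of both signs. Genes of the unfolded protein response fell (29 of 37 lower, adjusted p = 0.00157; adjusted p = 0.217 with an estimated correlation), among them herpud1, which helps degrade misfolded proteins, at -0.55 (SE 0.16), creld2 at -0.39 (-0.25 without AgNO3 replicate 4) and sesn2 at -0.43. Heat shock genes fell (24 of 33 lower, adjusted p = 0.0293; adjusted p = 0.443 with an estimated correlation), with dnajb1b at -0.34, hspa9 at -0.19 and bag3 at -0.21, while unc45b, a myosin chaperone, stood at 0.18 (0.11 without AgNO3 replicate 4). Innate immune, complement and acute phase genes fell (31 of 39 lower, adjusted p = 0.000490; adjusted p = 0.255 with an estimated correlation), led by mpeg1.1, a macrophage perforin, at -0.42 (SE 0.09), lygl1, a lysozyme gene, at -0.47, the collagenase mmp13a at -0.89 (-0.52 without AgNO3 replicate 4) and irg1l at -0.39. Genes of the glucocorticoid response fell (16 of 22 lower, adjusted p = 0.0279; adjusted p = 0.536 with an estimated correlation), with the steroid receptor co-chaperone fkbp5 at -0.58, klf9 at -0.45, sgk1 at -0.36 and the clock gene per1b at -0.42. Without AgNO3 replicate 2, fkbp5 stood at -0.36 and klf9 at -0.26, and without AgNO3 replicate 1, sgk1 stood at -0.24 and per1b at -0.25.

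Genes of the exocrine pancreas, of cartilage, bone and matrix and of fatty acid oxidation were higher as lists in AgNO3. Exocrine pancreas enzymes rose (20 of 24 higher, adjusted p = 0.00133; adjusted p = 0.443 with an estimated correlation), with the amylase amy2a at 0.38, the carboxypeptidases cpb1 at 0.25 and cpa1 at 0.27 (0.18 without AgNO3 replicate 1), and ctrb.3 at 0.43. Cartilage, bone and matrix genes rose (30 of 39 higher, adjusted p = 0.00133; adjusted p = 0.639 with an estimated correlation): matn4 was at 0.33 (0.20 without AgNO3 replicate 3), lum at 0.23 and the fin fold gene and3 at 0.47, while the collagen col11a1b was at -0.40. Genes of fatty acid oxidation rose (21 of 30 higher, adjusted p = 0.0279; adjusted p = 0.536 with an estimated correlation), with cpt1b, which brings fatty acids into mitochondria, at 0.54 and acads, etfa and acaa2 at 0.23, 0.22 and 0.19, the last with probes of both signs. No member of these 8 lists passed over all genes; adjusted over the list alone, 2 proteasome genes, 1 innate immune gene and 1 unfolded protein gene were lower, and 0 members of the other 5 lists passed. Leaving out 1 AgNO3 array ended the call of the matrix list (replicate 2 or 6), the pancreas list (1), the fatty acid list (1, 4, 5 or 6), the glucocorticoid list (1, 2 or 4) and the heat shock list (2, 4 or 6). With fry's test of whether a list moves 1 way on balance, the unfolded protein list passed (adjusted p = 0.0447) and the other 7 did not. Fry's mixed test asks for change in either direction, against no change rather than against other features. There the unfolded protein (adjusted p = 4.93e-16), proteasome (4.41e-06), glucocorticoid (0.00371), innate immune (0.00606) and heat shock (0.0451) lists passed. So did lists not called here, led by enterocyte (1.17e-08), photoreceptor (2.75e-08), epidermis (1.55e-05) and clock genes (3.05e-05). Scaling ended the calls of the glucocorticoid and heat shock lists, and array weights that of the glucocorticoid list. Leaving out features with gaps ended those of the fatty acid and heat shock lists, and leaving out the less variable features those of the matrix, fatty acid and proteasome lists. With the dye-swapped arrays turned, the matrix, unfolded protein, pancreas, glucocorticoid and heat shock lists did not pass and the fatty acid list passed the other way.

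The AgNPs arrays asked the same of silver given as particles. Expression of ace fell by 1.39 (SE 0.09, n = 6, adjusted p = 0.000449), lower on 6 of 6 arrays and with all 3 of its probes. The green cone opsin opn1mw1 was the only feature that rose past the threshold, by 0.86 (SE 0.08, adjusted p = 0.00663, 6 of 6 arrays higher). Expression of ciarta, a repressor of the circadian clock, fell by 0.82 (SE 0.11, adjusted p = 0.0475), guca1c fell by 0.73 (SE 0.09, adjusted p = 0.0247) and si:ch73-52f24.4 fell by 0.67 (SE 0.07, adjusted p = 0.00717), each lower on 6 of 6 arrays. A probe without a gene name fell by 1.15 (SE 0.13, adjusted p = 0.0181). At an unadjusted p under 0.05 there were 1072 features, 518 higher and 554 lower, against 1263.2 expected by chance. The spread shared by both groups in the model bears on this count as well. The call of ace held in 22 of 24 alternatives and those of opn1mw1 and si:ch73-52f24.4 in 20 of 23 each (both lost without AgNPs replicate 5), against 7 of 24 for ciarta and 12 of 23 for guca1c. Turning the dye-swapped arrays is not counted among these alternatives, and it ended all of these calls. With the 6 AgNPs arrays alone 0 features passed, with arrays scaled to a common spread 20 did, and without replicates 3 to 6, whose spread was narrow, 10 did, 0 of them shared with the 6. Replicates 1 and 2, the AgNPs arrays then left, both carried exposed RNA in Cy5. That setting therefore also changes the number of arrays and the dye balance.

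The genes next in line did not pass (adjusted p 0.0985 to 0.403). Of clock genes, cry2, a cryptochrome repressor, had a log2 ratio of -1.01 (SE 0.15), nr1d1, the nuclear receptor Rev-erb alpha, -0.99 (SE 0.15), and dbpa, a clock output factor, -0.43 (SE 0.07), whereas bmal1a, a core activator, had 1.09 (SE 0.21). Of photoreceptor genes, the red cone opsin opn1lw2 had 1.19 (SE 0.23) and the transducin subunit gngt1 0.45 (SE 0.09). Other values were 0.43 for gstt1b, a glutathione transferase, 0.56 for apom, an apolipoprotein, 0.40 for nutf2l, 0.55 for cdca7a and -0.71 for tdh, threonine dehydrogenase.

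Circadian clock genes fell as a list in AgNPs (23 of 31 lower, adjusted p = 1.89e-06; adjusted p = 0.143 with an estimated correlation), and the mean over the list was below 0 on 6 of 6 arrays. Of its members 1 passed over all genes, and 5 higher and 9 lower passed when adjusted over the list alone. Photoreceptor genes rose (32 of 45 higher, adjusted p = 0.000137; adjusted p = 0.0825 with an estimated correlation), although guca1c fell and pde6ga stood at -1.29 (SE 0.24). There 1 higher and 1 lower member passed over all genes, and 10 higher and 3 lower adjusted over the list alone. Antioxidant genes under Nrf2 and of glutathione metabolism rose (36 of 48 higher, adjusted p = 0.000598; adjusted p = 0.0825 with an estimated correlation), with the peroxiredoxin prdx1 at 0.35 (SE 0.08), gsto1 at 0.73 (SE 0.23) and gstm.3 at 0.22 (0.13 without AgNPs replicate 1). Cell cycle and DNA replication genes rose (26 of 34 higher, adjusted p = 2.46e-05; adjusted p = 0.227 with an estimated correlation), among them the DNA polymerase gene pold1 at 0.33 (SE 0.07), rrm1 at 0.29, and the replication helicase genes mcm7 at 0.33 (0.20 without AgNPs replicate 1) and mcm5 at 0.20. Of these, mcm5 had probes of both signs. Enterocyte genes fell (16 of 27 lower, adjusted p = 0.000598; adjusted p = 0.227 with an estimated correlation). Its members of lowest p carry nutrients and ions across the gut wall or digest peptides there. The peptide transporter slc15a1b was at -0.69 (SE 0.11), the anion exchanger slc26a3.2 at -0.82 (SE 0.14), the aminopeptidase anpepb.1 at -0.58 (SE 0.11) and the glucose transporter slc5a1 at -0.40 (SE 0.08).

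Other lists that passed in AgNPs were cytosolic ribosomal proteins (51 of 76 higher, adjusted p = 0.00593; adjusted p = 0.227 with an estimated correlation), with rps25 and rpl27 at 0.29, rps18 at 0.24 and rps19 at 0.19. The mean of the ribosomal list changed sign with the dye orientation. In AgNPs it was 0.0910 to 0.242 on the 3 arrays with exposed RNA in Cy5 and -0.110 to -0.0822 on the 3 in Cy3, and in AgNO3 it was 0.157 to 0.231 and -0.195 to -0.120. In values already turned, this pattern follows the dye. If the swapped arrays had not been turned before deposit, it would instead be a change in 1 direction on all 12 arrays, and turning was not settled. Only 3 of 6 AgNPs arrays were higher for rps25, 4 for rps18 and rps19 and 5 for rpl27. Myelin and glia genes rose (12 of 15 higher, adjusted p = 0.0189; adjusted p = 0.271 with an estimated correlation), with fabp7b at 0.30 (0.12 without AgNPs replicate 1), s100b at 0.20 (0.09 without 1) and slc1a2b at 0.16 (0.11 without 3 and 0.10 without 6) but the myelin glycoprotein gene mag at -0.45 (-0.16 without 6), where s100b and mag had probes of both signs. Cholesterol synthesis genes rose (16 of 23 higher, adjusted p = 0.0228; adjusted p = 0.402 with an estimated correlation), with insig1 at 0.40, hmgcra at 0.30 (0.17 without AgNPs replicate 1), fdps at 0.13 and hmgcs1, with probes of both signs, at 0.16. Adjusted over the list alone, 2 antioxidant, 1 cell cycle and 1 ribosomal gene were higher, 1 enterocyte gene was higher and 6 were lower, and 0 myelin or cholesterol genes passed; over all genes none of these 6 lists had a member past the threshold. The calls of the myelin list (without AgNPs replicate 1 or 6), the cholesterol list (1 or 5) and the ribosomal list (2) were lost with 1 array left out, and these 3 lists also did not pass with arrays scaled to a common spread. With fry, the clock, photoreceptor and antioxidant lists passed (adjusted p = 0.0435 each) and the other 5 did not. In fry's mixed test the enterocyte (adjusted p = 1.4e-09), photoreceptor (1.68e-09), clock (1.3e-06) and cell cycle (0.0106) lists passed, and the other lists called here did not. Without AgNPs replicates 3 to 6, the enterocyte, myelin, cholesterol and ribosomal lists did not pass. With the less variable features left out only the clock list passed, and with the dye-swapped arrays turned only the ribosomal list did. Array weights ended the calls of the cholesterol and myelin lists, a fit without dye term that of the ribosomal list, and the AgNPs arrays alone that of the myelin list.

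**Figure D3:**
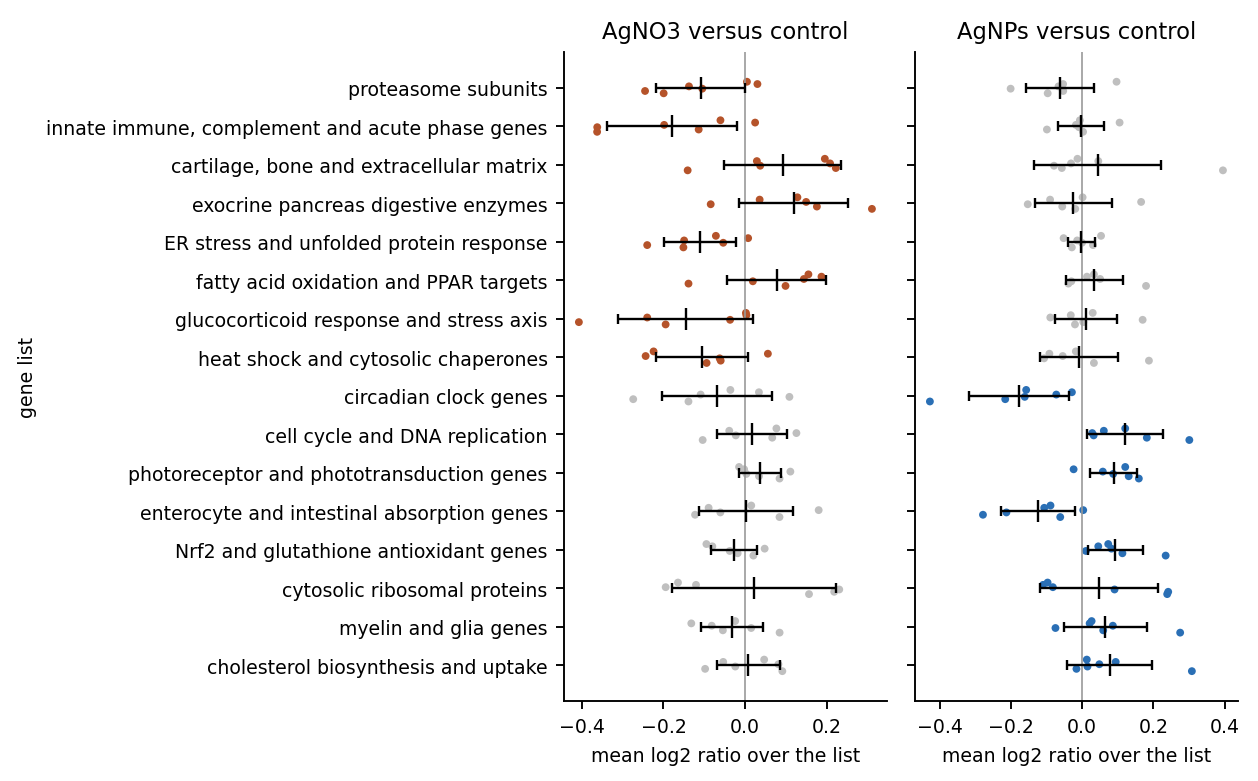
Mean log2 ratio over each gene list on each array (horizontal axis, points) for the lists that passed in either comparison (vertical axis), AgNO3 left and AgNPs right; bars are the mean over 6 arrays with its SD. Points are coloured where the list passed in that group with the preset correlation and grey where it did not.

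The salt and the particles were set against each other directly as AgNO3 minus AgNPs. No feature differed past the threshold in limma: the smallest adjusted p was 0.858, and 1066 features had an unadjusted p under 0.05 against 1263.2 expected by chance. Values of lowest p were those of hspa5, with a difference of -0.50 (95% interval -0.68 to -0.31), the embryonic globin gene hbae3 with -0.89 (-1.28 to -0.51), lsm6 with -0.48, rbmx2 with -0.42 and b4galnt1a with -0.71. In the other direction they were the clock output gene tefa with 0.83 (0.44 to 1.23), the coenzyme Q gene coq9 with 0.46, sec63 with 0.47, slc26a3.2 with 0.78 and ace with 0.59 (0.29 to 0.88). In AgNPs, hspa5, rbmx2 and b4galnt1a had probes of both signs, and so did tefa in AgNO3. Calls in 1 group only are therefore not shown to differ between groups: for grna.2 the difference was -0.50 (-0.73 to -0.27), for opn1mw1 -0.41 (-0.66 to -0.15), for si:ch73-52f24.4 0.37 (0.16 to 0.58), for ciarta 0.26 (-0.07 to 0.60) and for guca1c 0.14 (-0.13 to 0.41).

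As lists, 7 differed with the preset correlation and 0 with an estimated one. Enterocyte genes stood higher in AgNO3 than in AgNPs (23 of 27 higher, adjusted p = 0.00426; adjusted p = 0.380 with an estimated correlation). So did exocrine pancreas genes (18 of 24 higher, adjusted p = 0.00901; adjusted p = 0.412 with an estimated correlation) and clock genes (21 of 31 higher, adjusted p = 0.0364; adjusted p = 0.542 with an estimated correlation). Lower in AgNO3 were innate immune genes (35 of 39 lower, adjusted p = 0.00960; adjusted p = 0.380 with an estimated correlation) and cell cycle genes (26 of 34 lower, adjusted p = 0.0130; adjusted p = 0.509 with an estimated correlation). Lower too were unfolded protein genes (25 of 37 lower, adjusted p = 0.0130; adjusted p = 0.380 with an estimated correlation) and myelin genes (10 of 15 lower, adjusted p = 0.0453; adjusted p = 0.412 with an estimated correlation). Adjusted over the list alone, 1 pancreas, 1 clock and 1 unfolded protein gene differed, against 0 over all genes. Leaving out 1 array ended the call of the cell cycle list (AgNO3 replicate 1 or 3, AgNPs 1 or 2), the clock list (AgNO3 3 or 5, AgNPs 1, 2 or 6), the unfolded protein list (AgNPs 2) and the innate immune list (AgNO3 3). The call of the myelin list ended without any of AgNO3 replicates 2 to 5 or AgNPs replicates 1, 2 and 6, and with either block. With the less variable features left out, and with the dye-swapped arrays turned, none of the 7 lists passed. Scaling ended the calls of the pancreas and unfolded protein lists, and array weights those of the unfolded protein, cell cycle, clock and myelin lists. Without AgNPs replicates 3 to 6 the enterocyte, innate immune, unfolded protein and myelin lists did not pass, and without a dye term or with 1 per group the myelin list did not.

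Across 25264 features the changes of both groups correlated at r = 0.0599 (Spearman 0.0605), where genes are not independent replicates. Unchanged groups simulated against shared controls gave r = 0.0371 (SD 0.0112) and a covariance of 0.00117 beside an observed 0.00231. With 18 divisions of the arrays in which both groups used different control samples, r averaged 0.0494 (-0.0462 to 0.109) and the covariance 0.00279, against 0.114 and 0.00349 from all arrays over the same 17584 features. Calls overlapped in 1 gene, ace, against 0.000712 expected of independent lists. At an unadjusted p under 0.05, 104 features were lower in both groups (26.1 expected of independent lists; 41.2, SD 6.58, simulated with shared controls), 71 were higher in both (18.4 expected; 44.1, SD 6.90, simulated) and 18 went opposite ways (44.0 expected; 66.1, SD 9.05, simulated). The simulated features were independent of each other and had the same spread on every array. Measured features were correlated and array spreads differed, which tends to make the simulated SDs too small. How far the observed r and counts lie beyond chance is therefore not measured here.

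Genes known to respond to metals did not pass in either group. The metallothionein mt2 stood at -0.04 (SE 0.07) in AgNO3, with probes of both signs, and at 0.22 (SE 0.07, adjusted p = 0.947) in AgNPs; the heat shock gene hsp70l at -0.14 and 0.30 (SE 0.31 each); and the heme oxygenase hmox1a at -0.25 (SE 0.16) and 0.01 (SE 0.17, n = 5), the latter negative with scaled arrays. In AgNPs, hsp70l stood at 0.09 without AgNPs replicate 2, 0.16 without 5 and 0.46 without 1. In AgNO3, hmox1a stood at -0.09 without AgNO3 replicate 4 and -0.14 without 3. The metal handling list had adjusted p = 0.572 in AgNO3 and 0.541 in AgNPs. Of its members, fthl31, tfr1b and the copper transporter slc31a1, which had probes of both signs, stood at 0.32, -0.27 and -0.25 in AgNO3, and slc30a10 and ccs at -0.40 and 0.48 in AgNPs. Without AgNO3 replicate 2, slc31a1 stood at -0.14, and without AgNPs replicate 4, ccs stood at 0.27. The ion transport list had adjusted p = 0.963 and 0.541. There the ammonia channel rhcga stood at -0.57 (-0.37 without AgNO3 replicate 5) and the sodium pump subunits atp1a1a.2 and atp1a1a.4 at 0.28 and -0.20 in AgNO3, and atp6v1ba, ca2 and atp1b1a at -0.25, -0.17 and -0.28 in AgNPs, atp6v1ba and ca2 with probes of both signs (ca2 at -0.11 without AgNPs replicate 6). Further antioxidant values in AgNO3 were 0.33 for prdx1, -0.29 for gpx4a and -0.24, with probes of both signs, for abcc2, and further heat shock values in AgNPs were -0.74 for hsf2 (-0.47 without AgNPs replicate 5), -0.22 for hspa9 and 0.27 for hspa4b (0.16 without AgNPs replicate 1).

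The lists that passed in 1 group had these adjusted p-values in the other. In AgNPs they were 0.122 for proteasome, 0.858 for innate immune, 0.299 for matrix, 0.541 for pancreas, 0.848 for unfolded protein, 0.541 for fatty acid oxidation, 0.803 for glucocorticoid and 0.784 for heat shock genes. In AgNO3 they were 0.251 for clock, 0.764 for cell cycle, 0.0660 for photoreceptor, 0.572 for enterocyte, 0.701 for antioxidant, 0.285 for ribosomal, 0.572 for myelin and 0.701 for cholesterol genes. The clock members of lowest p in AgNO3 were dbpa at -0.38 (SE 0.07), ciarta at -0.56 (SE 0.11) and bhlhe41 at -0.62 (SE 0.12), each lower on 6 of 6 arrays.

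**Figure D4:**
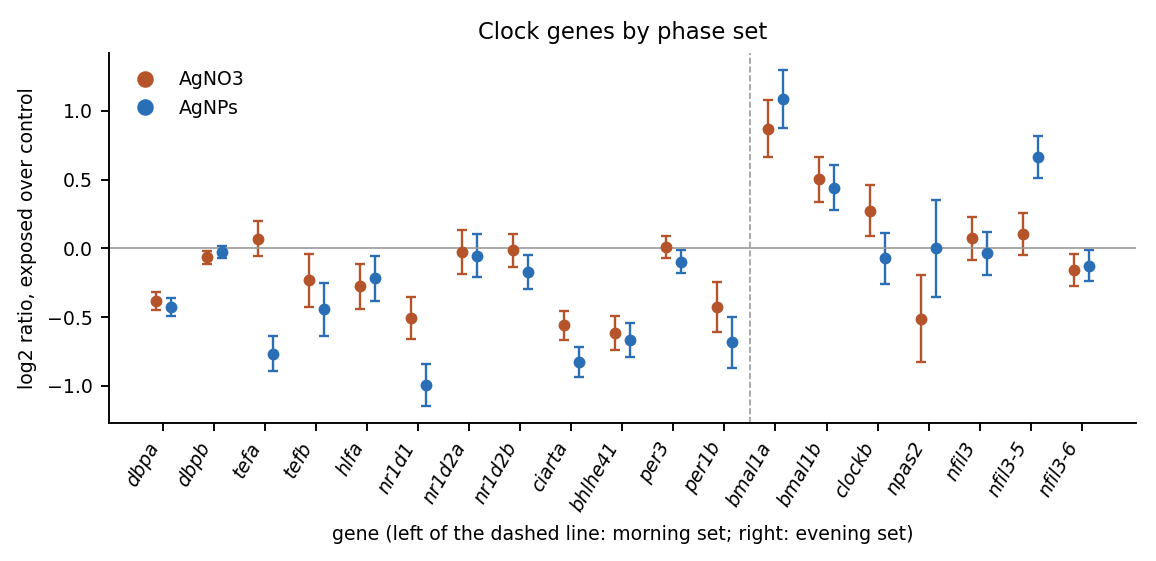
Log2 ratio of exposed over control larvae (vertical axis) for 19 clock genes (horizontal axis), points with SE of the model (n = 6 arrays per group, fewer where values were missing), AgNO3 and AgNPs in separate colours. The 12 genes left of the dashed line form the morning set and the 7 right of it the evening set, written after some of their values were seen; of all 19, ciarta in AgNPs passed an adjusted p of 0.05.

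The remaining 18 lists passed in neither group with the preset correlation, with adjusted p in AgNO3 and then AgNPs as follows. Among immune and blood genes they were 0.0577 and 0.438 for the interferon response, 0.617 and 0.830 for lymphocyte genes, and 0.164 and 0.803 for erythroid genes. Among stress and hormone lists they were 0.572 and 0.541 for p53 targets, 0.572 and 0.299 for aryl hydrocarbon receptor targets, 0.701 and 0.645 for estrogen response and yolk genes, 0.285 and 0.299 for hypoxia, and 0.285 and 0.102 for lysosome and autophagy. Among metabolic lists they were 0.296 and 0.438 for the respiratory chain, 0.891 and 0.560 for fatty acid synthesis, 0.701 and 0.541 for gluconeogenesis and fasting, and 0.572 and 0.438 for hepatocyte proteins. Among tissue markers they were 0.572 and 0.645 for fast muscle, 0.659 and 0.541 for slow and cardiac muscle, 0.572 and 0.229 for lens, 0.617 and 0.848 for neurons, 0.164 and 0.541 for epidermis, and 0.619 and 0.541 for pigment cells. Median, mean and test differed in sign in AgNO3 for the aryl hydrocarbon, fast muscle, slow muscle, hepatocyte, neuron, lymphocyte, estrogen, antioxidant, cholesterol, fatty acid synthesis and ion transport lists, and in AgNPs for the fatty acid synthesis, heat shock, erythroid, unfolded protein and innate immune lists.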

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

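The bound that kept the clock-phase test open was chosen only after its values were seen, and so were the probe-specific covariance by dye orientation and the exclusion of the AgNPs arrays of narrow spread.

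Of 193 groups of 6 values tested, 17 held an array far from the other 5, where chance marks about 1 in 20 groups and 9.65 were expected. In AgNO3, replicate 4 had 10.92% empty values (others 7.11 to 8.433). The log2 ratio of ppp1r3c2b was 0.2556 on replicate 6 (others 0.7595 to 0.8989), and on replicate 5 pde6ga was at -0.9703 (others -2.035 to -1.639) and rhcga at -1.525 (others -0.5587 to -0.2348). The mean of the lysosome list was -0.2373 on replicate 2, and that of the fast muscle list -0.1483 on replicate 1.

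In AgNPs, replicate 1 stood apart for mcm7 (1.027), fabp7b (1.14), s100b (0.8978) and gstm.3 (0.7392), and for the means of the matrix list (0.3953), the cholesterol list (0.3081) and the gluconeogenesis list (-0.08448). Replicate 6 stood apart for the red cone opsin opn1lw2, at 2.811 (others 0.6932 to 1.048), and for mag, at -2.008 (others -0.5151 to 0.03341). Replicate 2 did so for slc5a1 (-0.8664, others -0.3892 to -0.1829) and replicate 4 for hspa9 (-0.4175, others -0.2305 to -0.122). Replicate 1 was also among the 2 AgNPs arrays of wider spread, with an interquartile range of 0.293.

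The silver salt and the particles differed, by the test of the difference, in 7 gene lists with the preset correlation and in 0 with an estimated one (adjusted p 0.380 to 0.542). The median difference AgNO3 minus AgNPs was 0.1502 for exocrine pancreas genes, 0.118 for enterocyte genes and 0.1036 for clock genes. It was -0.1059 for innate immune genes, -0.1058 for myelin genes, -0.1009 for unfolded protein genes and -0.0976 for cell cycle genes. Of 100 divisions of the 12 arrays drawn from 200 with balanced dye orientation, 7, the real one included, called at least 7 lists, and the highest other called 10, so chance cannot be excluded. For single features the real division called 0 (limma; 1066 at an unadjusted p under 0.05), as many as or fewer than all 100 divisions, and the highest other called 1.

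Clock genes fell as a list in AgNPs with the preset correlation (camera adjusted p = 0.143 with an estimated one) and did not pass in AgNO3. The morning set (dbpa, nr1d1, ciarta, bhlhe41, per1b and 7 others, several of them seen lower before the set was written) had a median of -0.25 in AgNO3 and -0.44 in AgNPs. The morning-set mean was -0.47 on arrays with exposed RNA in Cy5 (SD 0.24) and -0.23 in Cy3 (SD 0.09), below 0 on 6 of 6 arrays each; this met the condition written against dye bias, but dye bias stays open, since it gives 1 sign on all arrays if the swapped arrays had not been turned before deposit, and the probe-specific covariance that speaks for turned values, -0.0150 between orientations (SE 0.00758), lay within 2 SE of 0. A single deciding array is argued against by the clock list in AgNPs, whose adjusted p with the preset correlation was at most 0.000514 whichever array was left out. A different clock phase at collection and an effect of silver on the clock cannot be told apart. The evening-set mean was above 0 on 6 of 6 arrays in each group (0.18, SD 0.17, in AgNO3 and 0.29, SD 0.15, in AgNPs). This goes with a phase difference but rests on few members. The highest were bmal1a (0.87 and 1.09), then bmal1b in AgNO3 (0.50) and nfil3-5 in AgNPs (0.66), while 2 of 7 members were lower in AgNO3 and 3 of 7 in AgNPs. The set had a median of 0.11 in AgNO3 and 0.0013 in AgNPs, which met the condition written for a phase difference. The AgNPs median is, however, near 0 over members going both ways, and collection times are not given in the sources used here.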

How the results depend on the processing

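Leaving out AgNPs replicates 3 to 6 was chosen only after the data were seen, and left AgNPs replicates 1 and 2, both with exposed RNA in Cy5. The counts of features called were unstable. In AgNO3 (3 called), 0 were called with scaled arrays, with array weights, with the arrays of the group alone, without AgNPs replicates 3 to 6 and with a log2 change of at least 1. There 1 was called with the less variable features left out and 1 with each probe on its own, neither among the 3. Leaving out 1 array gave 0 to 2 (1 without AgNO3 replicate 1 or 4, 2 without AgNPs replicate 1, 0 without any other). Turning the dye-swapped arrays gave 4, with 0 shared. In AgNPs (6 called), scaled arrays gave 20 (5 shared), array weights 10 (6 shared), leaving out AgNPs replicates 3 to 6 also 10 (0 shared), the less variable features left out 2 and a log2 change of at least 1 also 2. The arrays of the group alone and turned arrays gave 0. Leaving out 1 array gave 1 to 7, with 1 without AgNPs replicate 5 and 3 without AgNPs replicate 1 or AgNO3 replicate 1 or 4. The difference (0 called, limma; 1066 at an unadjusted p under 0.05) gave 7 without AgNPs replicates 3 to 6 and 0 to 1 with 1 array left out (1 without AgNO3 replicate 4). The size limit and the filter lower counts by their construction; for the other settings the cause was not tested.

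Of 8 lists in AgNO3, an estimated correlation called 0 and fry 1, and leaving out 1 array gave 5 to 11 (5 without AgNO3 replicate 4 or 6). Of 8 in AgNPs, an estimated correlation called 0, fry 3 and scaled arrays 5, and leaving out 1 array gave 6 to 9. The correlation between groups was 0.0228 to 0.103 with 1 array left out (0.0228 without AgNO3 replicate 4, 0.0333 without 5, 0.103 without 1). The cause was not tested. Among lists called, turning the dye-swapped arrays reversed the matrix, fatty acid and heat shock lists in AgNO3 and the myelin list in the difference; scaling reversed none. Leaving out the less variable features ended 3 of 8 list calls in AgNO3, 7 of 8 in AgNPs and 7 of 7 in the difference. Turned arrays ended 5, 7 and 7, array weights 1, 2 and 4, and scaling 2, 3 and 2.

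The replicate block left the counts of features in the 3 comparisons (3, 6 and 0) and of lists in both groups (8 and 8) as they were, and so did a block by control number. Either block ended the call of the myelin list in the difference, and the control number took the features called in both groups together from 15 to 14. Residuals from the group means correlated at -0.0491 to 0.0948 between arrays of the same replicate number, and at -0.147 to 0.0127 with dye orientation removed too. Arrays read as sharing a control gave -0.107 to -0.00486 by the first measure. It therefore did not pick up a pairing taken from the labels and cannot tell whether replicate numbers pair the arrays.

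Leaving out 1 array of the group moved 28 of 113 named values over 1.5 times, none of them a called gene. Signs reversed for 6 named genes, none called, over the settings other than turning the dye-swapped arrays, which was not tallied for named genes. Without AgNPs replicates 3 to 6, hmgcs1 was at -0.0096, slc1a2b at -0.024 and atp6v1ba at 0.057 in AgNPs. In AgNO3, mt2 ranged from -0.11 to 0.0041 with 1 array left out (positive without AgNO3 replicate 6) and hsp70l from -0.45 to 0.14 (positive without AgNO3 replicate 4). In AgNPs, hmox1a was at -0.019 without a dye term, -0.096 with scaled arrays and -0.018 with array weights. With 1 array left out it ranged from -0.053 to 0.086, negative without AgNPs replicate 1, 4 or 5 or AgNO3 replicate 4. The cause was not tested. Precision was limited by the number of arrays; signal over background is not given in the sources used here.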

Other observations

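The comparison of both silver groups together with control, the covariance between probes of the same gene, its gene bootstrap, its spread over arrays and its values by dye orientation were chosen only after the data were seen.

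Over all 12 arrays, the silver-exposed larvae of both groups differed from control in 15 features, 1 higher and 14 lower (1692 at an unadjusted p under 0.05 against 1263.2 expected). Vision genes stood at both ends: the green cone opsin opn1mw1 rose by 0.66 (SE 0.06), while pde6ga fell by 1.46 (SE 0.17) and guca1c fell by 0.66 (SE 0.06), each the same way on 12 of 12 arrays. The peptidase gene ace fell by 1.09 (SE 0.07), the intestinal peptide transporter slc15a1b fell by 0.59 (SE 0.08), tdh fell by 0.56 (SE 0.08) and si:ch73-52f24.4 fell by 0.49 (SE 0.05), all on 12 of 12 arrays. The clock genes ciarta, bhlhe41, dbpa and nr1d1 fell by 0.69, 0.64, 0.41 and 0.75 on 12 of 12 arrays, and grna.2 fell by 0.42 on 11 of 12. With the control number as a block 14 features passed, all but nr1d1 (adjusted p = 0.0540).

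Among lists, 12 passed in both groups together with the preset correlation and 0 with an estimated one. Photoreceptor genes rose and proteasome and clock genes fell (adjusted p = 0.000192 each with the preset correlation; adjusted p = 0.168, 0.240 and 0.240 with an estimated correlation). Matrix genes rose (adjusted p = 0.00200; adjusted p = 0.525 with an estimated correlation). The others were the cell cycle, ribosomal, fatty acid oxidation and antioxidant lists, higher, and the innate immune, unfolded protein, interferon and lysosome lists, lower. Of these the interferon and lysosome lists (adjusted p = 0.0378 each; adjusted p = 0.336 each with an estimated correlation) passed in neither group alone.

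Other divisions of the samples were counted for each result. In AgNO3, 1 of 32 sign patterns, the real one, called as many as 3 features and the highest other called 0. In AgNPs, 1 of 32 called as many as 6 and the highest other called 1. This share was under the 0.05 written against chance, but 1 in 32 is the smallest possible here. In AgNO3, the pattern that turned its dye-swapped arrays, with the dye term turned along, called 0. The separate fit with the swapped arrays of both groups turned and the dye term kept called 4. Most other patterns also lacked the balance of dye orientations of the real one, which lowers their power, so these counts do not exclude chance. For the lists chance cannot be excluded either: 2 of 32 patterns called at least 8 lists in AgNO3 and 4 of 32 in AgNPs, and the highest other called 8 in each. At an unadjusted p under 0.05, 3 of 32 patterns reached the 2084 features of AgNO3 (highest other 2192) and 7 of 32 the 1072 of AgNPs (highest other 1928). For both groups together, 6 of 100 patterns drawn from 2048 called at least 15 features, and the highest other called 38, so chance cannot be excluded. The 5 others called 21 to 38, and each followed the dye orientation on 9 or 10 of 12 arrays, a structure of the samples. Of lists, the real pattern of both groups together called 12 and the highest other of the 100 drawn called 10. No condition was written for this list count, the comparison was chosen after the data were seen, and most other patterns lacked the dye balance. It therefore does not exclude chance.

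A change shared by both silver groups was seen across genes. Between an AgNO3 and an AgNPs array with different control samples, the covariance between probes of the same gene was 0.00430 on average. Its 95% bootstrap interval over genes was 0.00329 to 0.00539, and its SE over arrays was 0.00189. This average narrowly argues against shared control RNA as the whole cause. It leans, however, on the 18 pairs of 1 dye orientation (0.00601, SE 0.00252), which a dye bias common to all probes of a gene would raise. Pairs with the same control were all of opposite orientation and gave 0.00434. The 12 pairs of opposite orientation with different controls gave 0.00174 (SE 0.00157), little above its SE. Among pairs of opposite orientation alone, shared control RNA therefore stays open as the cause. The bound written in advance, the SD over 30 single pairs (0.00555), was not exceeded by the average of 0.00430. That bound measures the spread of single pairs, not of their mean. Without the clock list, 94.1% of the covariance was left, so its members alone do not make it up. That list holds at most 34 of the 4897 genes behind the probe pairs, so this says little about genes outside it. A trend of probes of like spread is argued against by the 7.77e-05 (SD 0.000275) between matched probes of different genes. A response to silver common to both forms may explain the 0.00430, as may any difference between the control and the exposed tanks, which was not tested, or a dye bias common to all probes of a gene: with both orientations weighted equally, so that a dye bias cancels in turned values, the covariance was 0.00388 (SE 0.00177), but turning was not settled.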
